A study of Mus musculus with 2 samples.

How the data were processed

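DNase-seq measures where chromatin is open to cleavage by the nuclease DNase I. It was run on the embryonic facial prominence, the paired tissue swellings that form the face, of mouse embryos at 10.5 days of development, from B6NCrl animals of both sexes pooled. Per the labels there were 2 libraries of 1 group, given as biological replicates 1 and 2 from separate tissue samples with a shared donor code. The labels do not say how many embryos or litters each library held, so the spread between the libraries may be partly technical. The labels gave 2 sequencing instruments for replicate 1 and none for replicate 2. No condition was compared, and the comparisons the design allows are between the replicates, between regions of the genome and between groups of genes.

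Per the README deposited with each sample, every file was made from the library's own filtered alignment to mm10, so peaks were called per replicate and not on pooled reads. The aligner, the caller and their versions are not given in the sources used here. The authors deposited 3 peak lists per replicate. In 2 of them the peaks vary in width, and the deposited peak height is a signal that the authors scaled within each library. All heights of a library were whole multiples of a single step, within 0.05 steps, and the step of replicate 2 was 1.35 times that of replicate 1. The rule of this scaling is not given in the sources used here and the number of reads per library is unknown, so heights were used for ranks, correlations and differences between classes of regions. The third list holds peaks of up to 150 bp with whole-number heights, from a second filtered alignment. The deposited hotspots, which are broader enriched regions from that second alignment, carry a −log10 value capped at 100 and a score that is 10 times this value. The deposited FDR values (the p-value unit of these files) are given per run of bases for each alignment, and only bases under 0.05 are listed. The authors also deposited footprints, short protected stretches within accessible regions, whose score-like column holds 0.01 throughout.

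The thresholds of the peak lists were read by joining the peaks to the FDR files. Every peak of the first list held a base with an FDR under 0.001 (the highest value was 0.000997 in replicate 1 and 0.000993 in replicate 2), and this list was used throughout unless stated. Every peak of the second list held a base under 0.05. In the 150 bp list 7 peaks of replicate 1 and 4 of replicate 2 held no listed base. Some peaks of a list overlap each other, and the 109661 and 83390 peaks merged to 106358 and 77559 intervals. The summit column of the files did not vary, so peak centres were used.

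All peak ends lay inside the chromosomes of GRCm38 on 21 of 21 chromosomes. Genes were the 21911 protein-coding genes of GENCODE M21, with 93444 transcription start sites (TSS), after 27 duplicated symbols were left out. A promoter ran from 1000 bp upstream to 500 bp downstream of any annotated TSS. Peaks were classed by their centre as promoter, exon, intron or intergenic, in this order. Peaks of both replicates were joined into regions, and a region counted as shared when it held a peak of each replicate. Distal regions overlapped no promoter and were given to the gene with the nearest TSS within 100 kb. Overlap required 1 bp, and chance overlap came from 100 circular shifts of the peaks along their chromosomes. Intervals of shares are exact Clopper-Pearson 95% intervals, which cover counting error only.

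Before the data were examined, 16 gene lists (352 genes) were fixed: transcription factors of facial mesenchyme, frontonasal and mandibular regional genes, facial ectoderm, facial signalling, orofacial cleft genes, later skeletal genes, neural and olfactory genes, crest-derived neurons and glia, muscle, endothelium, blood, transcription factors of other tissues, differentiation genes of other tissues, Hox genes and housekeeping genes. Some genes are in several lists. The share of a list's genes with a promoter peak in both replicates was set against 10000 random gene lists of the same size matched on the decile of promoter CpG content (observed over expected). The median number of shared distal regions per gene was set against lists matched on the decile of the length of sequence nearest to the gene's TSS. This is a permutation test of gene labels within each decile, drawn without replacement. The p-values are two-sided, cannot fall below 0.0002, were adjusted over the 16 lists by the Benjamini-Hochberg method, and describe these 2 libraries, since genes are not replicates. The density of shared distal regions of facial mesenchyme and other-tissue transcription factors was compared by a two-sided permutation test with 100000 resamples.

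The text names, by a rule fixed with the lists, up to 4 members of each list with the most shared distal regions and up to 2 in alphabetical order with no promoter peak in either replicate, the 10 genes with the most shared distal regions, the 5 shared regions with the highest mean rank of height, up to 5 of the 1000 highest peaks of a replicate absent from the other, and the 5 motifs with the highest and the 3 with the lowest mean ratio. Names outside this rule are given as such, and some genes that the rule takes are not reported here.

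The 27 fixed consensus motifs were matched on both strands in 150 bp windows at the centres of distal peaks. Background windows were centred 1000 bp to each side, outside the hotspots of both replicates. Each ratio of shares was also ranked among up to 200 shuffles of the consensus. For footprints, widened to at least 20 bp, the background was a window of the same width in the same peak outside any footprint. A ratio of at least 1.5 in both replicates was counted as enriched. Where the background held 0 matches the ratio was computed against 3 matches and is a lower bound, a treatment chosen after the first ratios were seen.

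The functions were tested on simulated data. With 70% of peaks kept in place the overlap came out at 70.2%, and a simulated correlation of 0.9 at 0.901. Of 5 lists raised in distal regions 0 were called at 2-fold, 1 at 3-fold and 4 at 5-fold, and of 5 lists lowered at promoters 5 were called. No list among 11 unchanged ones was called in any of these runs. The motif matcher differed from regular expressions in 0 of 54000 comparisons. Alternatives to each choice were the other peak lists, hotspots in place of peaks, 50% reciprocal overlap, equal numbers of peaks, other promoter windows (500 and 2500 bp), assignment limits of 20 kb and 1 Mb, other backgrounds and motif windows, and each replicate alone. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 were used.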

Results

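Chromatin accessibility was profiled in the embryonic facial prominence of mouse embryos at 10.5 days, a stage at which the face is built of neural crest-derived mesenchyme covered by ectoderm. The 2 replicate libraries gave 109661 and 83390 peaks with a median width of 200 and 220 bp, which covered 24.3 and 22.8 Mb. The deposited hotspots numbered 150288 in replicate 1 (65.1 Mb) and 114368 in replicate 2 (58.1 Mb), and the footprints 507772 and 432574. The read depth of the libraries is unknown, so the difference in these numbers could not be set against depth.

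The replicates shared the highest peaks and parted at the low ones. The region with the highest mean rank of height lay in an exon of Lars2, the mitochondrial leucyl-tRNA synthetase (mm10 chromosome 9, 123461981 to 123462060), with heights of 41.4 and 30.8. It was followed by the promoter of Hjurp, a centromeric histone chaperone (chromosome 1, 88277461 to 88277740, heights 54.1 and 19.5), intergenic regions nearest to Cr2 (chromosome 1, 195241541 to 195241820) and Cd209a (chromosome 8, 3754381 to 3754560), and the promoter of Myo10 (chromosome 15, 25622241 to 25622580). The Lars2 region was 80 bp wide and lay 7231 bp from the nearest protein-coding TSS. No regions were removed here as prone to excess signal, so artefacts of alignment among the highest regions were not excluded. Of the 1000 highest peaks of either replicate, 0 were absent from the other.

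Of the replicate 1 peaks 65.6% (95% interval 65.3 to 65.8) overlapped a replicate 2 peak, and of the replicate 2 peaks 85.1% (84.9 to 85.4) overlapped a replicate 1 peak, against 1.55% and 2.09% for shifted peaks. The overlap was larger for higher peaks, from 7.31% in the lowest decile of replicate 1 peaks to 99.4% in the highest, and from 39.1% to 99.8% in replicate 2. Against the other replicate's longer list at an FDR of 0.05, 80.8% and 90.4% of the peaks were found. In the lowest decile of height this share was still 15.6% for replicate 1 and 56.7% for replicate 2. Joined peaks gave 112894 regions, of which 64275 (56.9%) were shared. Across the shared regions, which are not independent replicates, heights correlated with a Spearman rho of 0.937 and a Pearson r of 0.942 on the log2 scale. Hotspots of the replicates had 64.9% of their joint length in common.

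**Figure D1:**
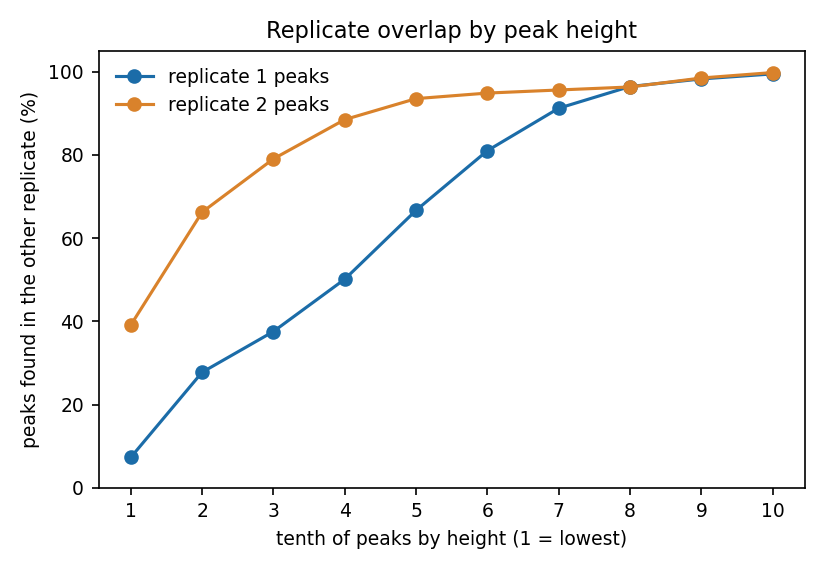
Share of the peaks of each replicate that overlapped a peak of the other replicate (vertical axis, percent) by decile of peak height (horizontal axis, 1 is the lowest). The share ran from 7.31% to 99.4% for replicate 1 and from 39.1% to 99.8% for replicate 2.

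Promoters held 27.9% ± 4.35 (SD, n = 2) of the peaks, with 24.8% in replicate 1 and 30.9% in replicate 2, where shifted peaks gave 3.05% and 3.01%. Introns held 29.4% ± 1.85 and intergenic sequence 37.4% ± 2.68, both under the shifted shares of 35.0% and 59.0% in replicate 1. The shared regions were promoters in 31.3% of cases, the regions of replicate 1 alone in 9.62% and those of replicate 2 alone in 20.3%. Shared promoter regions were also the highest class, with a median height of 4.04 in replicate 1 and 1.95 in replicate 2, against 1.14 and 0.860 for intergenic regions. A promoter peak was present in both replicates at 14653 of 21911 protein-coding genes (66.9%), in replicate 1 alone at 403 and in replicate 2 alone at 91.

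Promoters of genes that build the face were accessible. All 41 transcription factor genes of facial mesenchyme had a promoter peak in both replicates, as did all 8 frontonasal and 12 mandibular regional genes, all 37 facial signalling genes and all 24 housekeeping genes, while CpG-matched random lists had means of 94.5% to 97.8%, so near the ceiling that the test could not have called these lists higher. Genes that mark differentiated cells of other organs rarely had one: 2 of 36 (5.56%) had a promoter peak in both replicates, against a mean of 31.3% in CpG-matched random lists (adjusted permutation p = 0.0016, from the smallest p that the random lists can give). Members without a promoter peak in either replicate included Alb and Apoa1, which encode the liver products albumin and apolipoprotein A-I. Hox genes, which set position along the body axis, were the other list to pass the test as lower, with 19 of 39 (48.7%) against 91.0% (adjusted permutation p = 0.0016). They lie in clusters, and Hoxc5 and Hoxc10 had the same promoter heights (5.28 in replicate 1 and 3.08 in replicate 2). The random lists draw genes singly, so this p-value, like that for Hox distal regions below, takes linked genes as independent.

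The Hox call rested on replicate 2, where 51.3% of the promoters had a peak. In replicate 1 alone the share was 84.6% (adjusted permutation p = 0.383), a peak in either replicate gave 87.2% (p = 0.797), and random lists not matched on CpG content gave p = 0.0534, with 0.0016 to 0.797 over all alternatives. The call on differentiation genes of other organs held in each replicate alone, with 8.33% in replicate 1 and 5.56% in replicate 2. The remaining lists did not pass the test. Facial ectoderm genes had a promoter peak in 19 of 22 cases, with Krt5, the basal keratinocyte keratin, without a peak. Cleft genes had peaks in 27 of 28 cases, neural and olfactory genes in 20 of 22 (Dcx, of migrating neurons, had no peak) and crest-derived neuron and glia genes in 11 of 12. Other-tissue transcription factors had peaks in 34 of 40 cases, with 5 members closed in both replicates, among them Crx of photoreceptors. Later skeletal genes had peaks in 11 of 16 cases (Bglap, which encodes osteocalcin, and Col10a1, of hypertrophic cartilage, had no peak), endothelial genes in 11 of 16 (Cdh5 and Emcn had no peak), muscle genes in 7 of 14 (Acta1 and Chrna1 had no peak) and blood genes in 5 of 18 (Alas2 and Csf1r had no peak). With a promoter of 2500 bp to each side the muscle list passed the test as higher (78.6%, adjusted permutation p = 0.0256, with 0.0256 to 1 over all alternatives). With random lists not matched on CpG content 7 lists passed as higher and the blood list as lower.

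Regulators of the facial mesenchyme had more distal regions around them than other genes with domains of like length. The transcription factors of this list had a median of 9 shared distal regions per gene, against 2 in matched random lists (adjusted permutation p = 0.000457, from the smallest p that the random lists can give), with 17 in replicate 1 alone and 11 in replicate 2 alone. Hand2, a bHLH factor of the branchial arches (chromosome 8, 57320983 to 57324633), had 30, Tfap2a, an AP-2 factor of neural crest and ectoderm (chromosome 13, 40715302 to 40738376), had 25, Pax3 had 22 and Meis2 had 20. Frontonasal genes had a median of 10.5 regions, led by Pax3, the nuclear receptor gene Nr2f1 (18), Pax7 (15) and the homeobox gene Six2 (14). Mandibular genes had a median of 7, led by Hand2, the homeobox genes Barx1 (20) and Dlx6 (11), and Hand1 (10). Facial signalling genes had a median of 6, led by the retinoic acid receptor gene Rara (19), Axin2 of the Wnt pathway (16), Gli2 of the hedgehog pathway (14) and Spry2, an antagonist of FGF signalling (12). Cleft genes had a median of 5.5, led by Tfap2a, Msx1 (20), Foxe1 (14) and the adhesion gene Nectin1 (12). The medians in replicate 1 alone and replicate 2 alone were 16 and 14 for frontonasal, 15.5 and 9 for mandibular, 9 and 7 for signalling and 9 and 6.5 for cleft genes.

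The excess was not limited to the facial lists. Neural and olfactory genes had a median of 6.5 distal regions, led by Sox1 (20), Sox2 (16), Six3 (16) and Lhx2 (15), and other-tissue transcription factors 5.5, led by Pax2 of the kidney (31), Onecut1 of the liver (17), Tlx1 of the spleen (17) and Tbx4 of the hindlimb (14). Crest-derived neuron and glia genes had a median of 4, led by Foxd3 (10), Mitf (10) and Pou4f1 (9). Muscle genes had a median of 3, led by Tcf21 (8) and 3 genes with 6 regions, Chrna1, Myh3 and Des. Hox genes had a median of 1 region, in domains with a median length of 10.1 kb, led by Hoxb13 (20), Hoxb9 (16), Hoxc4 (15) and Hoxa13 (13). The medians in replicate 1 alone and replicate 2 alone were 9 and 9.5 for neural and olfactory, 9.5 and 9.5 for other-tissue, 5 and 4.5 for crest-derived, 5.5 and 4 for muscle and 4 and 1 for Hox genes. These 10 lists of this and the preceding paragraph were higher than their matched random lists, with adjusted permutation p from 0.000457 to 0.0246.

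The other 6 lists did not pass the test. Facial ectoderm genes had a median of 2 distal regions (adjusted permutation p = 0.171), with 14 at Foxe1, 11 at Grhl2 and 8 at Wnt7b. Later skeletal genes had a median of 2.5, with 12 at Sox5 and 11 each at Col1a1, Col1a2 and Sox6, and endothelial genes 2.5, with 8 at Erg and Flt1, 7 at Fli1 and 6 at Cdh5. Housekeeping genes had a median of 1, with 9 at Ywhaz, 8 at Eef1a1 and 4 at Actb. Blood genes and differentiation genes of other organs had a median of 0, with 4 at Tal1, 3 at Ptprc, 2 at Spi1 and 1 at Klf1 among the former, and 6 at Ins2 and 2 each at Scgb1a1, Dazl and Ttr among the latter. The medians in replicate 1 alone and replicate 2 alone were 5 and 3 for ectoderm, 6 and 4 for skeletal, 4 and 4 for endothelial, 1.5 and 1 for housekeeping, 1 and 0.5 for blood and 1 and 0 for differentiation genes. Against the 16 lists pooled as background, without a match on domain length, the facial mesenchyme and frontonasal lists stayed higher, the blood list (adjusted permutation p = 0.016) and the differentiation list (p = 0.0032) were lower, and the other 8 calls ended. Of 8 alternatives the facial ectoderm list passed as higher in 5, the skeletal list in 6 and the endothelial list in 3. In replicate 2 alone all of these lists passed (adjusted permutation p = 0.023, 0.0233 and 0.0256), and in replicate 1 alone the ectoderm (0.0016) and skeletal (0.0128) lists did. The crest-derived call ended in replicate 1 alone (adjusted permutation p = 0.129), with the list at an FDR of 0.05 (0.0678) and with a limit of 20 kb (0.754), and the Hox call with the list at an FDR of 0.05 (0.0701) and with unmatched lists (1). Over all alternatives the adjusted permutation p ran from 0.0016 to 0.87 for ectoderm, 0.00924 to 0.971 for skeletal, 0.0256 to 0.971 for endothelial, 0.002 to 0.87 for crest-derived, 0.0004 to 1 for Hox, 0.016 to 1 for blood and 0.0032 to 1 for differentiation genes.

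**Figure D2:**
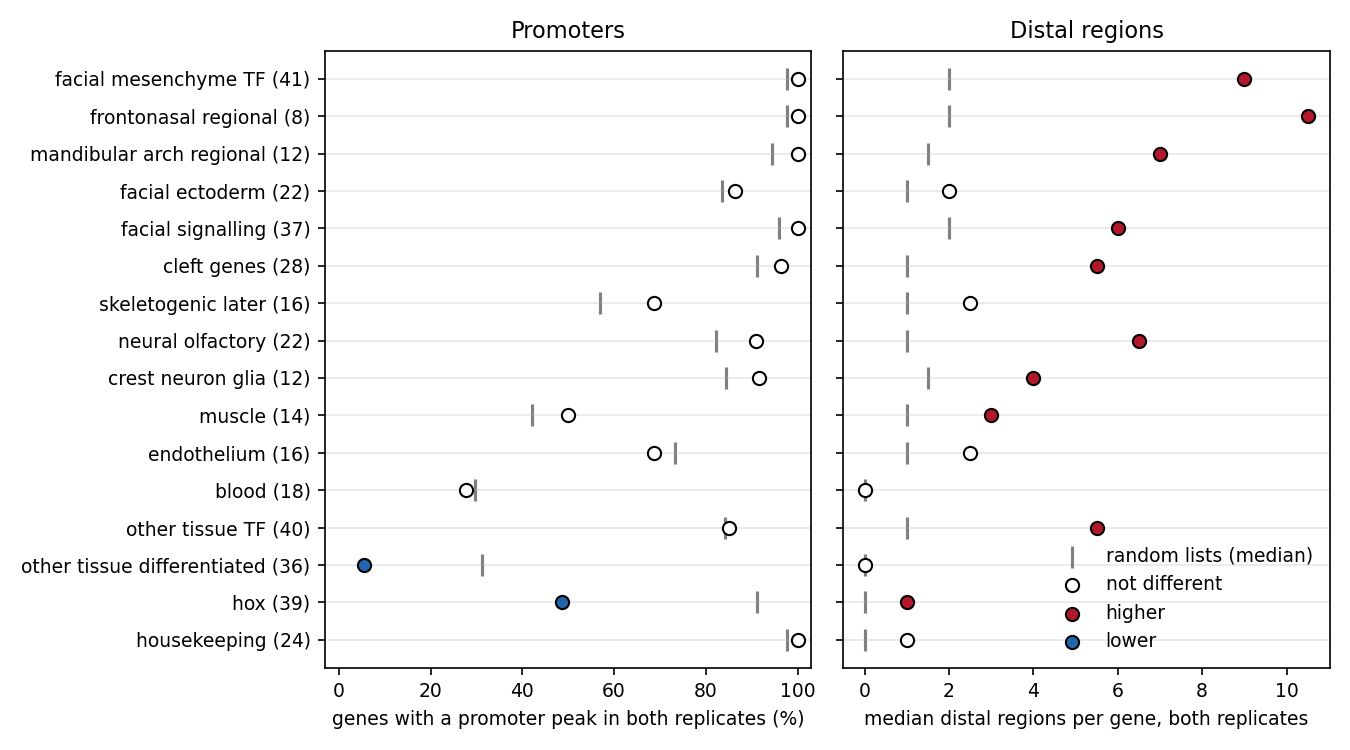
Share of genes with a promoter peak in both replicates (left, percent) and median number of shared distal regions per gene (right) for the 16 gene lists, with the number of genes in brackets. Grey bars give the mean (left) and the median (right) of 10000 matched random lists, and filled points passed the test at an adjusted p of 0.05. Of the lists, 2 were lower at promoters and 10 were higher in distal regions.

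Among all genes, the most shared distal regions lay at Bcor, which encodes a BCL6 corepressor (37 regions, chromosome X), followed by Gse1 (36), the T-box gene Tbx3 (34), Pax2 (31), Hand2 (30), the nuclear receptor gene Nr2f2 (28), the homeobox gene Uncx (27), Bahcc1 (26), Zic4 (26) and Casz1 (25). The median gene had 1 shared distal region and 10410 genes had 0.

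Transcription factors of the facial mesenchyme and of other tissues were then compared with each other, which holds the class of gene fixed. The facial factors had 10.1 ± 10.3 (SD over 41 genes) shared distal regions per 100 kb and the other-tissue factors 7.97 ± 6.85 (40 genes). The difference of 2.11 per 100 kb was within the spread of genes (two-sided permutation p = 0.299). In replicate 1 alone it was 5.10 (permutation p = 0.187) and in replicate 2 alone 0.728 (permutation p = 0.814). In numbers per gene in place of density the facial factors had 3.17 more regions (permutation p = 0.0336), but these numbers are not adjusted for domain length. The median domain was 134 kb for facial and 88.2 kb for other-tissue factors. Median densities of shared distal regions were 6.95 and 6.36 per 100 kb. No expression was measured here, so any other-tissue factors that are also active in facial tissue could not be left out.

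The Hox clusters differed between the replicates. In replicate 1 a promoter peak was present at 9 of 11 Hoxa genes (chromosome 6, 52155590 to 52260880), 8 of 10 Hoxb genes (chromosome 11, 96194316 to 96368256), 7 of 9 Hoxc genes (chromosome 15, 102921103 to 103036852) and 9 of 9 Hoxd genes (chromosome 2, 74668310 to 74765142). In replicate 2 the numbers were 6, 6, 4 and 4. Peaks per 100 kb numbered 66.5 in replicate 1 and 34.2 in replicate 2 at Hoxa, 39.7 and 19.01 at Hoxc, 106 and 50.6 at Hoxd, and 40.2 and 42.5 at Hoxb. The share of each cluster under hotspots was 52.2% and 27.2% at Hoxa, 27.2% and 30.3% at Hoxb, 28.2% and 14.5% at Hoxc, and 75.6% and 42.4% at Hoxd. Hoxa9 and Hoxa11 were among the 5 Hox genes without a promoter peak in either replicate. With 1 library on each side there is no test of this difference.

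**Figure D3:**
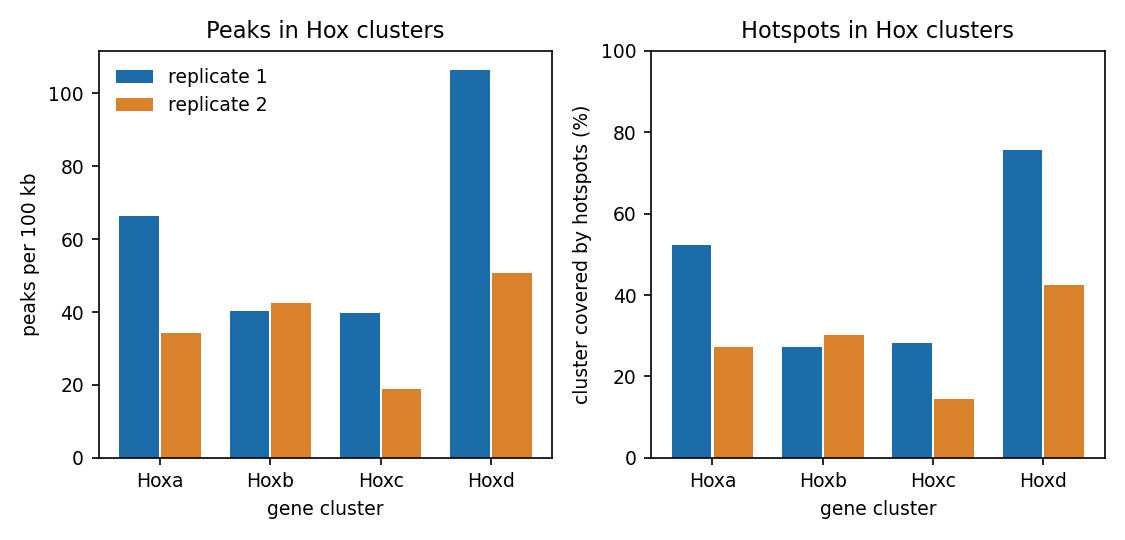
Peaks per 100 kb (left) and percent of the cluster covered by hotspots (right) in the 4 Hox clusters, for each replicate, with 1 library per bar and no error bar. Replicate 1 held more peaks than replicate 2 at Hoxa, Hoxc and Hoxd, and at Hoxb the values were 40.2 and 42.5 peaks per 100 kb.

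Among the 27 motifs, those of CTCF and REST stood highest in distal peaks. The motif of CTCF, the architectural protein of insulators, was in 6.53% of distal windows of replicate 1 and 8.47% of replicate 2, which was 149 (interval 114 to 200) and 185 (133 to 264) times the share in flanking windows. The motif of REST, a repressor of neuronal genes, was in 143 windows of replicate 1 and 139 of replicate 2 and in 0 flanking windows, at least 70.4 and 65.9 times the flanking share. NFI followed with ratios of 9.08 and 3.32, from 43 and 14 windows, SP with 6.69 and 5.47 and NRF1 with 5.84 and 4.18. The lowest ratios were those of HNF1, a liver and kidney factor (0.0923 and 0.547, from 1 and 5 windows), the paired-type homeodomain palindrome (0.395 and 0.444) and GATA (0.508 and 0.559). In both replicates 11 of the 27 motifs had a ratio of at least 1.5, and 11 exceeded 95% of their shuffles, with 6 in both sets. Among the latter 11, SP had only 8 shuffles and TAATTA 13, too few to resolve 95%, and each exceeded all of its own. NRF1 exceeded 61.5% and 49% of its shuffles and NFI 97% and 85%, and 4 motifs that exceeded 95% of their shuffles had ratios under 1.

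Distal windows were richer in GC than the flanks, with 53.8% against 44.6% in replicate 1 and 53.3% against 44.7% in replicate 2. With flanks matched on GC content the mean ratio of SP was 1.93, of NRF1 2.76 and of GATA 0.996, and the direction turned for the homeodomain palindrome (2.39). Outside the naming rule it also turned for MEF2 (0.703 to 1.95), forkhead (0.868 to 1.47), SOX (0.907 to 1.19) and RUNX (0.858 to 1.15). The p63 motif stayed under 1 (0.792 and 0.769). The grainyhead-like motif, named after its values were seen, had ratios of 4.29 and 3.62, from 90 and 56 windows. It exceeded 100% and 98.5% of its shuffles, and its mean ratio was 3.96 with adjacent and 5.02 with matched flanks. Against the matched flanks HNF1 had 0.661 in replicate 1 and 4.41 in replicate 2. NFI was at 0.985 among the 10000 highest distal peaks. That value rests on few matches, since all distal peaks held 43 and 14 and their flanks 7 and 6. Motifs of facial regulators, named after their values were seen, differed in how far they depended on the GC match. The AP-2 motif had ratios of 2.71 and 2.51, below its median shuffle of 4.55 and 4.51, and 1.24 in both replicates against GC-matched flanks. The PBX-MEIS motif had a mean ratio of 2.33 with adjacent and 2.73 with matched flanks, the motif of Six2 and related factors 4.16 and 5.37, the TWIST E-box 1.37 and 1.29, and a joint E-box and homeodomain site reported in cranial neural crest 0.962 and 2.02. The TAATTA homeodomain site had 0.597 and 0.595, above all 13 of its shuffles, and 2.05 and 1.84 against GC-matched flanks.

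**Figure D4:**
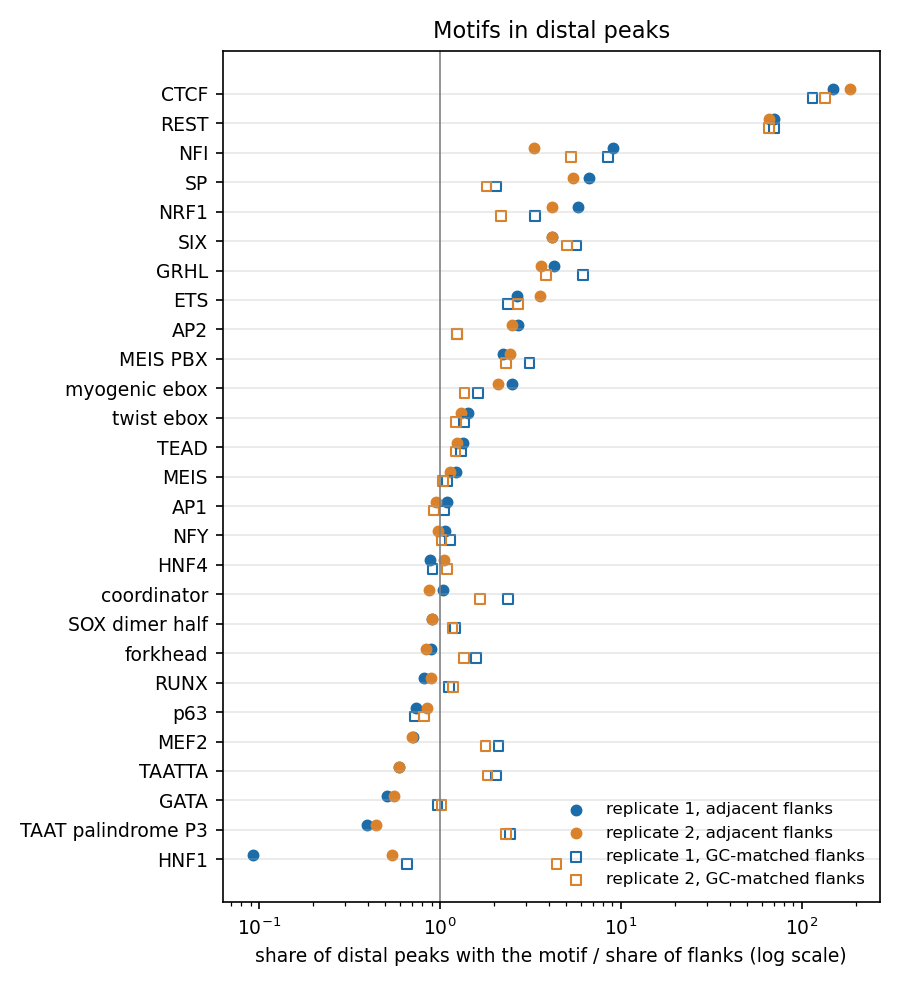
Share of distal peaks with each of the 27 motifs divided by the share of flanking windows, on a log scale, for each replicate. Filled circles use adjacent flanks, open squares flanks matched on GC content, and the values of REST are lower bounds because 0 flanking windows matched. The ratio of CTCF was 149 and 185, and the homeodomain palindrome lay under 1 with adjacent flanks and above 1 with matched flanks.

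The same 5 motifs led in footprints. The footprint ratios cover all peaks, promoters included, and had neither a GC match nor a rank among shuffles. The CTCF motif was in 1.499% and 1.57% of the footprints inside peaks, 196 (interval 132 to 306) and 278 (171 to 487) times the share in windows of the same peaks outside footprints. NRF1 was in 347 footprints against 1 background window in replicate 1, a ratio of 347 (interval 61.9 to 13745), and in replicate 2 the ratio was at least 121. REST reached at least 48.0 and 48.3. The ratio of NFI was at least 10.3 in replicate 1, and 15 in replicate 2 with an interval of 2.31 to 631. SP had ratios of 13.4 and 11.1. HNF1 was in 0 footprints of either replicate, against 0 and 1 background windows, so it had no mean ratio. Of the other motifs the lowest ratios were those of forkhead factors (0.303 and 0.309), p63 (0.316 and 0.520) and GATA (0.515 and 0.537). Motifs of facial regulators were again named after their values were seen. AP-2 had footprint ratios of 2.03 and 1.76, the TWIST E-box 1.58 and 1.39, and TAATTA 1.34 and 1.13. PBX-MEIS had 0.674 and 0.784, from 29 footprints in each replicate, with intervals of 0.406 to 1.11 and 0.465 to 1.31. The motif of Six2 and related factors had 0.844 and 3.4. The joint E-box and homeodomain site had 1.58 and 1.125, from 19 and 9 footprints. The grainyhead-like motif had 1.15 and 1, from 47 and 24 footprints. In both replicates 7 of the 27 motifs had a ratio of at least 1.5, in replicate 1 alone 11, and 4 when motifs with 0 background matches were left out.

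The footprints had a median width of 10 bp in replicate 1 and 9 bp in replicate 2, and 65.3% and 67.8% of them overlapped a peak. Footprints of replicate 1 overlapped one of replicate 2 in 41.2% of cases, and footprints of replicate 2 one of replicate 1 in 50.2%. Inside peaks the overlap was 49.6% and 59.1%, against 35.4% and 39.5% when footprints were moved at random within their peak.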

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

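The alternative that left out motifs with 0 background matches was chosen after the result was seen, and all other alternatives were fixed earlier. In all 448 alternatives to 64 results were computed. Of the alternatives to values that answer a comparison 62 stayed, 25 moved and 1 became stronger, with 0 reversed. Here a tested value stayed when it kept its side of the threshold, and a count when it changed by 1.5-fold at most. Other values stayed when they moved by less than their spread. For overlaps this spread was the SD of the shares of the 2 replicates, which also reflects their unequal numbers of peaks. Of those to single lists and motifs 285 stayed, 14 lost their call, 25 gained one, 31 moved and 5 reversed. The cause of these changes was not tested, except where the construction of the alternative shows it.

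A stricter overlap of 50% of both intervals lowered the shared peaks to 46.6% and 61.5%, the shared hotspots to 47.2% and 62.1% and the shared footprints to 28.8% and 33.8%, and gave a Spearman rho of 0.932. With equal numbers of peaks 79.8% of replicate 1 peaks were shared. The rank correlation was 0.940 with the peak list at an FDR of 0.05 and 0.760 over all regions with 0 for a missing peak. Among hotspots with a −log10 value of 10 or more, 95.6% of those of replicate 2 were shared. Footprints inside peaks were shared in 49.6% and 59.1% of cases. The promoter share was 41.0% with windows of 2500 bp to each side, 20.03% with the list at an FDR of 0.05 and 19.9% with the 150 bp list.

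For promoters, 1 list was higher with windows of 2500 bp and 7 without the match on CpG content. The number of lower lists was 1 with a peak in either replicate, and 1 to 2 with a replicate left out, the lower number without replicate 2. For distal regions, pooling the 16 lists as background left 2 lists higher and 2 lower and turned the direction of muscle genes (median 3, adjusted permutation p = 1, with 0.00107 to 1 over the alternatives) and Hox genes (median 1, adjusted permutation p = 0.167, with 0.0004 to 1 over the alternatives). The 14 lost calls included the Hox promoter list, in 3 settings. Facial against other-tissue factors passed the test in numbers per gene (3.17, permutation p = 0.0336, with a range of 0.0336 to 0.814 over the alternatives). These numbers are not adjusted for domain length. Hox promoters with a peak numbered 20 to 33 with a replicate left out. The number of motifs enriched in footprints was 8 to 11 with a replicate left out and 4 without motifs that had 0 background matches, and in distal peaks the latter gave 10. NFI was at 0.985 in the 10000 highest distal peaks, a value from few matches, and GC-matched flanks raised the homeodomain palindrome to 2.39. The HNF1 mean of 2.54 with these flanks came from 0.661 in replicate 1, still under 1, and 4.41 in replicate 2, with 1 and 5 distal windows.

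Stricter footprint scores were not run, because the score column holds a single value. No paired analysis was possible because there is 1 group. The unknown read depth limits how far the lower number of peaks in replicate 2 can be read.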

Other observations

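The tests of limb bud, trunk and second arch cells, with their comparison to other-tissue regulators, of heights in the Hox clusters, of peak height, and of GC content with height, and the comparison with sets of windows, were chosen after the result or related values were seen. Chromosome X stood below all autosomes in peak height in both replicates. Its shared regions had a median height of 0.929 in replicate 1 and 0.680 in replicate 2, whereas the lowest autosome, chromosome 14, had 1.29 and 0.983 and the highest, chromosome 11, had 1.75 and 1.22. Chromosome X held 15.9 and 12.8 peaks per Mb, and chromosome 11 held 64.3 and 50.5. Both libraries were from pooled sexes, and no biological explanation was tested because the design holds 1 group.

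Replicate 1 held more Hox cluster peaks than replicate 2. No biological explanation was tested because the design holds 1 group, and of the technical ones, cells of other body regions mixed into replicate 1 were weighed with limb bud genes (9 genes, among them Tbx5, Fgf10 and En1) and trunk genes (13 genes, among them Cdx2, Tbx6 and Meox1), of which Tbx4, Tbx5, Lhx9, Cdx1, Cdx2, Tbx6, T and Mnx1 are also in the other-tissue list. Their replicate 1 peaks were found in replicate 2 more often than expected from class, height and CpG content, by 8.79 and 5.97 percentage points (percentiles 98.0 and 94.1 of random lists). The peaks of 30 other-tissue regulators outside these lists lay further above expectation, by 15.5 points, and among draws of as many of these regulators the limb bud list was at percentile 7.68 and the trunk list at 0.43, so limb bud and trunk cells stay open. Of the 27 promoters of Hox groups 5 to 13, 21 had a peak in replicate 1 and 11 in replicate 2. In replicate 1 alone 11 had one and in replicate 2 alone 1, which argues against second arch cells as the whole cause. In groups 1 to 4 all 12 had a peak in replicate 1 and 9 in replicate 2. Over all genes, promoter peaks in a single replicate were also more frequent in replicate 1 (403 against 91). Second arch cells as part of the cause are not excluded. No sort or gate is given in the labels. Another candidate explanation that stays open is that lower peaks missed the threshold in replicate 2: at equal class and height, Hox peaks were found -8.67 percentage points from expectation, at percentile 34.1 of 1386 windows of 100 kb with at least 15 replicate 1 peaks, a choice that favours windows rich in replicate 1, and 22.8 of sets of 4 windows chosen on either replicate, and matching on CpG content left -9.39, no nearer to 0, so CpG content is not settled. The windows vary widely (SD 13.95 points), and Hoxb (28.2 points) went against Hoxa (-22.9), Hoxc (-21.2) and Hoxd (-17.8), so a difference confined to some clusters was not excluded. Heights did not follow the peak numbers: the 130 shared regions in the clusters had a median log2 ratio of replicate 1 to replicate 2 of -0.17 (SD 0.46), against 0.53 (SD 0.59) for all shared regions, and lay 0.47 below regions of like class and mean height (percentile 1.53 of 1109 windows of 100 kb), with -0.57 at Hoxa, -0.40 at Hoxb, -0.45 at Hoxc and -0.50 at Hoxd. Regions without a replicate 2 peak have no height there, so this value does not decide between the open explanations. Low ratios were not confined to the Hox clusters, before any match on class or height. Regions of other-tissue transcription factors had a median log2 ratio of 0.07 (SD 0.44) and those of neural and olfactory genes 0.06 (SD 0.49). Regions of Hox genes were the lowest of the 16 lists (-0.18), and only those of housekeeping genes lay above all shared regions (0.81).

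Over all shared regions, the median height ratio of replicate 1 to replicate 2 was larger at promoters than elsewhere. The difference was 0.61 on the log2 scale (SD 0.05 over 20 chromosomes), and no biological explanation was tested. By decile of mean height, the promoter ratio lay under that of other regions in deciles 1 to 5, with -0.065 against 0.048 in decile 1. It lay above that of other regions in deciles 6 to 10, with 1.57 against 1.27 in decile 10. Matched on GC content the difference was 0.40 (SD 0.06) and matched on mean height 0.29 (SD 0.06), and neither value decides whether either property alone is the cause. Matched on both together, the third match tried, it was 0.13 (SD 0.05), which is consistent with a joint technical dependence on GC content and height. Mean height includes the ratio's own terms, so this match may remove part of any true difference.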
